A study of Mus musculus with 8 samples.

How the data were processed

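RNA from 8 mouse regulatory T (Treg) cell samples was sequenced, with 2 libraries in each of 4 genotypes. The cells carried a Foxp3-driven Cre recombinase with a YFP reporter and were sorted from spleen and lymph nodes that had been pooled. WT cells carried the Cre alone, RelB-KO cells lacked Relb, Nfkb2-KO cells lacked Nfkb2 and DKO cells lacked both genes. All were cultured for 16 h with plate-bound antibody to CD3 at 5 µg/ml, soluble antibody to CD28 at 1 µg/ml, an agonist antibody to OX40 at 2 µg/ml and IL-2 at 10 ng/ml. Total RNA was made into TruSeq libraries, and the design gives 30 M reads per sample. The labels do not say whether the replicates came from separate animals, so adjusted p values here measure only the spread between these libraries.

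The deposited table holds log2 expression values for each gene and library, and its header calls them log2 RPKM, batch corrected. The labels name STAR, the mm10 genome and DESeq2 1.10.1 without giving their roles, and the counting program, annotation and batch method are not stated. The values did not behave as RPKM. Multiplied by exonic length in kilobases, the un-logged values summed to between 110.2 and 114.2 M per library, against at most 1 M for RPKM, and alone they summed to between 18.2 and 19.7 M. Genes with little expression had nearly the same value in every library, as a shrunken log transform gives. The scale is treated here as log2 expression relative to library size. Counts were not used here, so the depth behind each value is unknown and no counting interval is given. A shrunken scale makes fold changes of weakly expressed genes too small. The authors also deposited log2 fold changes and p values with adjusted p values of each knockout against WT, which are given as the authors' where they are used. Z-scores in the same table were not used here.

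The table lists 22432 genes. Of these, 6247 were listed at 0 in all libraries and were left out, as was Zwilch, which had a blank cell. The 13797 genes with a mean un-logged value of at least 1 were tested. For 25 genes the symbol had been turned into a date, and none of them is named here.

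Before the data were examined, the comparisons, tests, gene lists, rule for named genes and most alternatives were fixed. That plan gave a count-based test for counts and, for normalized values, limma on log2(value + 1). The deposited values were already on a log2 scale, so limma 3.58.1 in R 4.3.3 was fitted to them as deposited, and the pseudocount of 1 became an alternative. A linear model with the 4 genotypes was fitted to all 8 libraries, with empirical Bayes moderation and a trend of variance on expression, leaving 4 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 13797 genes, separately for each of 7 contrasts. These were each knockout against WT, the 3 comparisons among knockouts, and the interaction (DKO minus Nfkb2-KO, less RelB-KO minus WT).

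Replicate numbers were checked for pairing. The difference between replicate 1 and replicate 2 was correlated across genes between genotypes, with Pearson coefficients from 0.81 to 0.89 in the 6 pairs of genotypes. The first principal component held 67.8% of the variance and separated the replicate numbers. Libraries with the same number and another genotype correlated at 0.997 to 0.999, and those of the same genotype at 0.993 to 0.994. The replicate difference is therefore still present in the batch-corrected values. The planned model has no term for it. A second model with replicate number as a block, with 3 residual degrees of freedom, was planned as an alternative, and its value is given as "with the replicate block" beside the gene counts and beside some of the list results that it changes.

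Tested on simulated data with the observed spread, the model without the block recovered 16% of changes of 0.5 log2 units, 76% of changes of 1 and 94% of changes of 2, with 0 false calls among 13797 genes. With the block it recovered 82% of changes of 0.5 and 100% of larger changes, with 28 false calls. At each size (0.5, 1, 2 and 4) 50 changes were planted, and with the block 41, 50, 50 and 50 were recovered. The 28 false calls were thus a larger share of the calls with the block than the adjusted p threshold of 0.05 aims for. Counts of called genes with the block may therefore hold more false calls than that threshold implies. Simulated libraries with no change gave 0 calls without the block and between 0.81 and 1.28 calls on average with it, with a maximum of 11. All simulations used normal noise at the spread of the model with the block and the same replicate shift in every genotype. Changes were planted only in genes above a minimum mean expression, so recovery of weakly expressed genes was not simulated.

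Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 21 lists. Camera with an estimated correlation and the rotation test fry were run beside it. At the estimated correlation or with fry 0 lists passed in any of the 7 contrasts, so every list call below rests on the preset correlation. The 23 lists with 447 members covered NF-kB pathway components, NF-kB target genes, the Treg signature, effector Treg genes, resting T cell genes, helper T cell cytokines and lineage regulators, chemokine receptors and adhesion, the TNF receptor superfamily, cell cycle, apoptosis, interferon-stimulated genes, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, stress and immediate-early genes, ribosomal proteins, mitochondrially encoded genes, T cell identity, and markers of B cells, myeloid and dendritic cells, CD8 T and NK cells, and erythroid cells. Mitochondrially encoded genes (0 of 13 in the table) and erythroid markers (2 of 12 tested) were too few to test. Some genes are in more than 1 list.

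Named genes were chosen by a rule. Relb and Nfkb2 came first. For each comparison the rule then took up to 10 called genes with the largest positive and up to 10 with the largest negative log2 fold change. They had to pass an expression minimum (a deposited value of 6.23 on average, standing for a log2 CPM of 2) and to show no overlap between the libraries of the groups compared. Predicted genes and antigen receptor segments were passed over. The rule also took up to 4 members with the smallest p of each list described, up to 10 genes for the interaction, and Foxp3, Il2ra, Ctla4 and Il10 in each comparison with WT. Xist, Ddx3y and the genes of the authors' RelB-KO calls are outside the rule and were named after their values were seen. Coordinates are from GENCODE M21 on GRCm38, the same assembly as mm10, and each value covers the whole annotated gene.

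Alternatives were no filter on low values, a mean un-logged value of at least 32, a log2 fold change of at least 1, only the libraries of the groups compared, each library left out in turn, quantile normalization, a pseudocount of 1, lists without X- or Y-linked members and without Relb and Nfkb2, correlations over called genes or genes of at least 4 per 1 M alone, the authors' adjusted p values, and leaving out genes with a near-identical copy. Copies were found with minimap2 2.31-r1302 by aligning 12178 genes to 10256 processed pseudogene transcripts and to other coding genes, at an identity of at least 95% over at least 200 bases. The definition of a coding copy was changed after its first run so that neighbouring genes that overlap at the same locus no longer counted. Another count-based test and other size factors, which need counts, were not run.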

Results

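The series asked how loss of the alternative NF-kB pathway changes the transcriptome of Treg cells, the Foxp3-expressing T cells that restrain immune responses. Relb and Nfkb2 encode the pathway's transcription factor subunits. The Nfkb2 product is a precursor that holds RelB in the cytoplasm until it is processed to RelB's partner. Expression was compared in WT, RelB-KO, Nfkb2-KO and DKO Treg cells stimulated through CD3, CD28 and OX40 with IL-2, with n = 2 libraries per genotype. Values are deposited log2 expression values, and the depth of each library is unknown beyond the 30 M reads per sample of the design. Fold changes are differences on this log2 scale ± the standard error of the limma model, and a gene was called at an adjusted p under 0.05 over 13797 genes. If no gene changed, a share of about 0.05 of these genes would have an unadjusted p under 0.05.

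Transcripts of the targeted genes were low where the labels place each deletion. Relb (chromosome 7, 19606217 to 19629438, minus strand, mm10) averaged 10.58 ± 0.12 (SD, n = 2) in WT and 10.84 ± 0.01 in Nfkb2-KO, against 6.44 ± 0.12 in RelB-KO and 6.91 ± 0.24 in DKO. Nfkb2 (chromosome 19, 46304320 to 46312385, plus strand) averaged 12.71 ± 0.12 in WT and 12.49 ± 0.26 in RelB-KO, against 8.77 ± 0.03 in Nfkb2-KO and 9.57 ± 0.40 in DKO. No library overlapped between the deleted and the intact groups for either gene. Nfkb2 shares part of its annotated locus with Psd. Foxp3, the lineage-defining transcription factor (chromosome X, 7573644 to 7595245), lay between 13.95 and 14.28 in all 8 libraries. WT replicate 1 differed from the other libraries in sex-linked transcripts, with Xist at 8.17 against 14.6 to 15.1 and Ddx3y at 11.60 against 4.25 to 4.35.

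**Figure D1:**
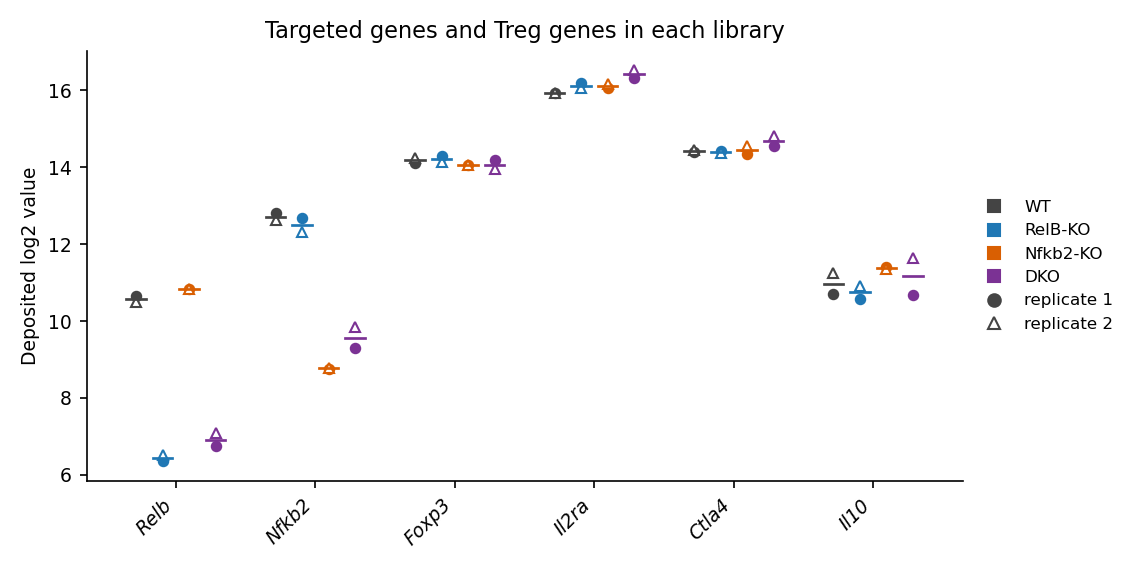
Deposited log2 expression values (y axis) of the targeted genes and 4 Treg genes in each library, with 1 point per library and a bar at the mean of each genotype (n = 2). Relb lay at 7.08 or lower in RelB-KO and DKO and at 10.49 or higher in the other groups, and Foxp3 stayed between 13.95 and 14.28.

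**Figure D2:**
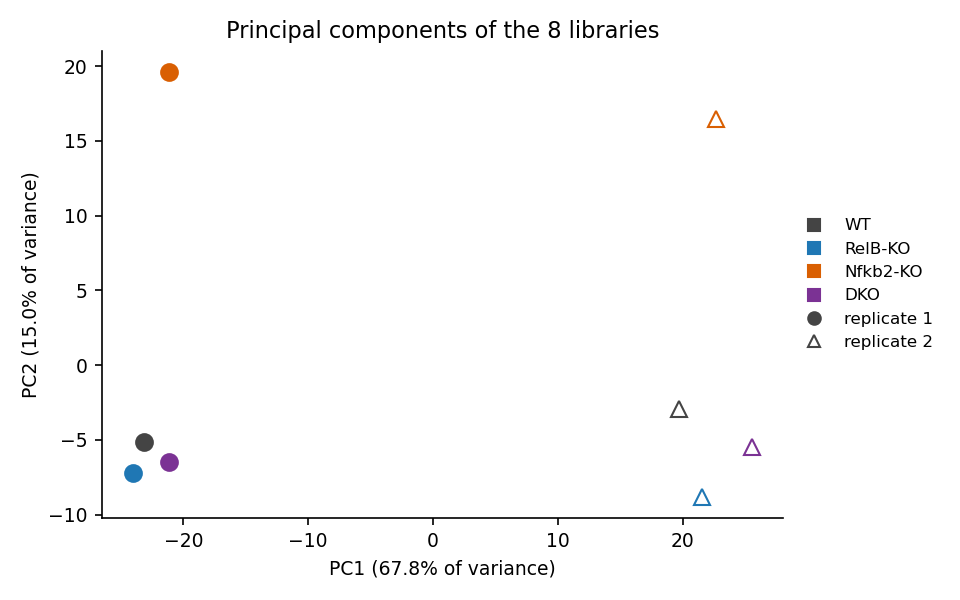
Scores of the 8 libraries on the first 2 principal components of the tested genes, each axis labelled with its share of variance. The first component (67.8%) separated replicate 1 from replicate 2 in every genotype, and the second (15.0%) placed the Nfkb2-KO libraries, at 19.6 and 16.5, apart from the others, which lay between -8.80 and -2.96.

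Loss of Nfkb2 alone changed the expression of more genes than loss of RelB alone. Compared with WT, Nfkb2-KO cells had more Thsd7a, a thrombospondin-repeat membrane protein (2.87 ± 0.35, adjusted p = 0.0448), Sh3pxd2b, a podosome adaptor (2.49 ± 0.17), Dscam, an adhesion molecule (2.45 ± 0.23), and Scin, an actin-severing protein (2.27 ± 0.24). Aldh1a2, which makes retinoic acid (chromosome 9, 71215789 to 71296243, plus strand), rose by 2.26 ± 0.12 (adjusted p = 0.00465), from 6.35 ± 0.07 (SD) to 8.61 ± 0.16. Hspg2, the matrix proteoglycan perlecan (2.15 ± 0.20), Whrn, a scaffold protein (1.88 ± 0.17), Vcam1, an adhesion molecule (1.71 ± 0.17), Pcyt1a, an enzyme of phosphatidylcholine synthesis (1.65 ± 0.21), and Fsd1l (1.496 ± 0.16) rose as well. Cd74, the class II invariant chain, rose by 1.45 ± 0.17. Pcyt1a shares part of its locus with Slc51a. Fewer genes fell, and in the model without the replicate block the 7 called lower were Nfkb2 itself (-3.94 ± 0.20), Gbp1, an interferon-induced GTPase (-1.51 ± 0.19), Il6ra, the IL-6 receptor alpha chain (-1.24 ± 0.11), Matk, a tyrosine kinase (-1.14 ± 0.13), Matn2, a matrix protein (-1.07 ± 0.12), Plxnd1, a semaphorin receptor (-0.98 ± 0.11) and Fam101b (-0.89 ± 0.11). For each gene named so far in this comparison both Nfkb2-KO libraries lay on the same side of both WT libraries.

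In all, 47 genes were called between Nfkb2-KO and WT, 40 higher and 7 lower, and 1472 had an unadjusted p under 0.05. With the replicate block 402 were called (264 higher, 138 lower), including all 47, and the authors' adjusted p values call 739 (415 higher, 324 lower), including 46 of the 47. Genes added by the block included Myo3b, a myosin (1.91 ± 0.20), Pde2a, a phosphodiesterase (-1.63 ± 0.16), the cytotoxic granule protease Gzmb (-1.49 ± 0.15), Syne2 (-1.41 ± 0.16), and Satb1, a chromatin organizer (-1.28 ± 0.16). Without the block the count moved with every library: it was 0 without WT replicate 1 and 29 without WT replicate 2. It was 4 and 14 without Nfkb2-KO replicate 1 and 2, and 10 to 12 without any of the RelB-KO or DKO libraries.

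**Figure D3:**
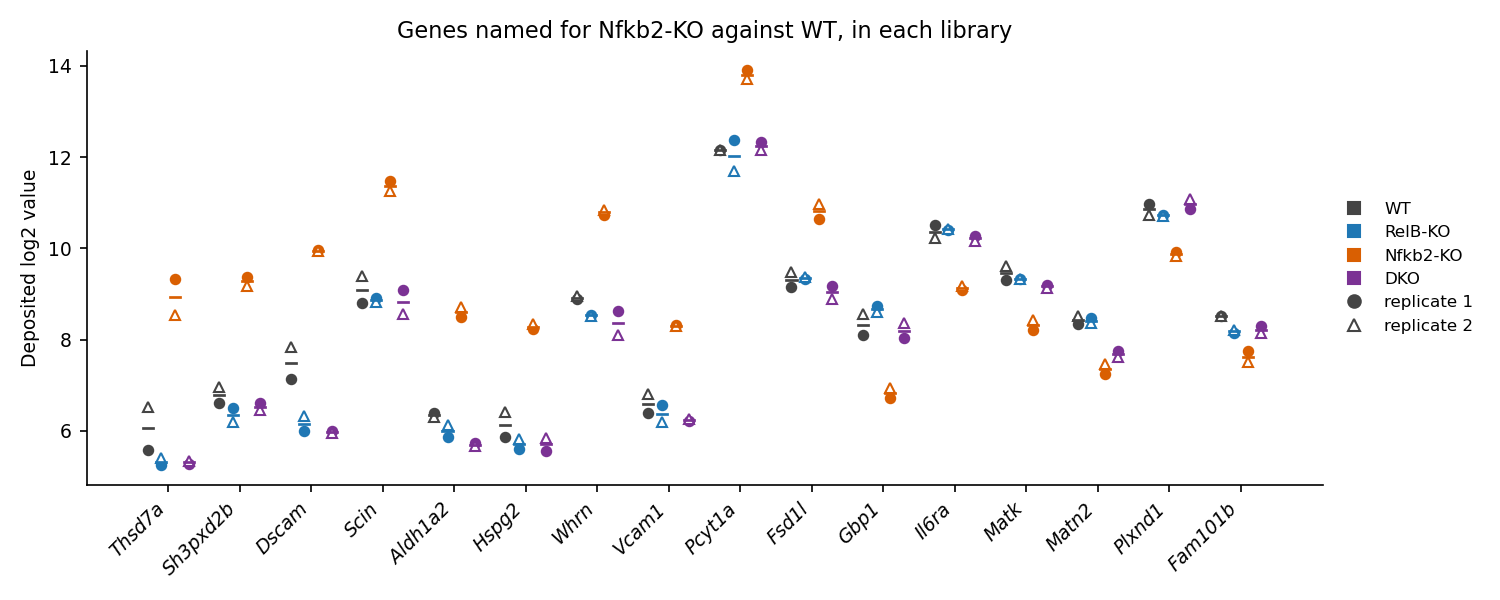
Deposited log2 expression values (y axis) of the genes named for Nfkb2-KO against WT, Nfkb2 left out, with 1 point per library, colour for genotype, shape for replicate number and a bar at each mean (n = 2). For Aldh1a2 the Nfkb2-KO mean was 8.61, against 6.35 in WT, 6.00 in RelB-KO and 5.70 in DKO.

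Among the fixed lists, the resting T cell genes were lower in Nfkb2-KO than in WT. Of 17 measured, 15 were negative (median -0.51), 1 fell when adjusted over all genes (Il6ra) and 7 fell when adjusted over the list alone. These included Satb1 (-1.28), the lymph-node egress receptor S1pr1 (-0.64) and Foxp1 (-0.64), and camera gave an adjusted p of 1.52e-06 (adjusted p = 0.54 with an estimated correlation). NF-kB target genes were higher as a set (19 of 23 positive, median 0.22, adjusted p = 0.000741, and adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone, 3 rose (Bcl2a1a 0.47, Ltb 0.48, Nfkbie 0.62) and Irf1 fell by 0.47, while 0 passed over all genes with limma, and 4 rose and 1 fell with the block. NF-kB pathway components, which include Nfkb2, had a positive median (0.10) and a mean of -0.01. Birc2 (0.81), Traf2 (0.37) and Nfkbie were among 4 that rose in the list alone, and camera called the set higher (adjusted p = 0.0141, and 0.585 as the adjusted p with an estimated correlation).

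Helper T cell cytokines were higher in Nfkb2-KO than in WT (adjusted p = 0.00552, and adjusted p = 0.54 with an estimated correlation). Il21, a helper T cell cytokine, rose by 1.07 ± 0.12 over all genes, and Il17a (0.47) passed when adjusted over the list alone, where 5 rose with the block. Lineage regulators were not called as a set (adjusted p = 0.43), although 5 of 17 passed when adjusted over the list alone. Il23r (0.51) was among those that rose, while Cxcr5 (-0.81) and Bcl6 (-0.86), which mark follicular T cells, fell. Chemokine receptors and adhesion genes were lower (median -0.14, adjusted p = 0.00552, and adjusted p = 0.54 with an estimated correlation), with Cxcr5 and S1pr4 (-0.51) falling when adjusted over the list alone. Interferon-stimulated genes were lower (19 of 23 negative, median -0.16, adjusted p = 0.000663, and adjusted p = 0.572 with an estimated correlation). Of these, Gbp2 (-1.26) and Gbp3 (-0.76) passed over the list alone.

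All 22 oxidative phosphorylation genes were positive in Nfkb2-KO against WT (median 0.16, adjusted p = 0.000441), as were 19 of 21 cholesterol biosynthesis genes (median 0.14, adjusted p = 0.000663). With an estimated correlation the adjusted p values were 0.572 and 0.54, and 0 genes of either list passed on their own, over all genes or over the list alone with limma. With the block 6 cholesterol biosynthesis genes rose and 1 fell over the list alone, and 0 of the oxidative phosphorylation genes passed. Stress and immediate-early genes were also higher as a set (median 0.19, adjusted p = 0.0141, and adjusted p = 0.572 with an estimated correlation). Sets not called included the Treg signature (median 0.05, adjusted p = 0.147), effector Treg genes (0.08, adjusted p = 0.351), cell cycle (-0.21, adjusted p = 0.343), apoptosis (0.06, adjusted p = 0.343) and glycolysis, whose median (0.07) and mean (-0.01) differed in sign (adjusted p = 0.47). With the block the cell cycle list was called lower (adjusted p = 0.00956) and ribosomal proteins higher (5.69e-05, against an adjusted p of 0.358 without it), and with an estimated correlation these gave adjusted p values of 0.738 and 0.598. Ribosomal protein genes such as Rps13 (-5.29) and Rpl9 (-5.26) were far lower in replicate 1 in every genotype. Reads shared with pseudogene copies may lie behind this, so the ribosomal protein values under that call are in doubt.

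Tnfrsf11a, the receptor RANK, was called higher (1.01 ± 0.13) in the TNF receptor superfamily, a list with a median of 0.01 that was not called (adjusted p = 0.735). Markers of other cell types were measured beside these groups. B cell markers had a median of 0.00 (adjusted p = 0.101), myeloid and dendritic cell markers -0.01 (adjusted p = 0.669), CD8 T and NK cell markers 0.02 (adjusted p = 0.935) and T cell identity genes -0.03 (adjusted p = 0.47). In the B cell list Cd74 and, adjusted over the list alone, Blk (0.21) and H2-Ab1 (0.55) rose. Foxp3 (-0.11 ± 0.12), Il2ra (0.17 ± 0.13), Ctla4 (0.02 ± 0.13) and Il10 (0.41 ± 0.33) differed from WT by less than the test could call, and under quantile normalization Il2ra came to 0 and Ctla4 to -0.09.

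Loss of RelB alone left few differences that passed the test. Relb itself was the 1 gene called between RelB-KO and WT (-4.14 ± 0.13, adjusted p = 0.000347), with 171 genes at an unadjusted p under 0.05, fewer than no change would give. With the replicate block Serpina3g, a serine protease inhibitor, was also called (-0.96 ± 0.08, adjusted p = 0.00959), from 11.29 ± 0.27 (SD) in WT to 10.34 ± 0.13. The authors' adjusted p values call 13 genes, 3 higher and 10 lower. By their log2 fold changes the higher genes were Pparg (0.79), Gsto1 (0.58) and Ebi3 (0.58), and the lower ones besides Relb and Serpina3g included Dscam (-1.35), Rln3 (-1.004), Ifng (-0.87), Marcksl1 (-0.74), Cxcr3 (-0.53) and Ltb (-0.45). The count was 12 (1 higher, 11 lower) without WT replicate 2, and 1 without any other library.

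Helper T cell cytokines were lower in RelB-KO as a set (12 of 18 negative, median -0.05, adjusted p = 0.00482, and adjusted p = 0.857 with an estimated correlation). Ifng (-0.78 ± 0.18) and Il17a (-0.34 ± 0.09) had the smallest p values and did not pass when adjusted over the list alone. With the block 2 members fell over the list alone. CD8 T and NK cell markers were lower beside them (10 of 12 negative, median -0.05, adjusted p = 0.0526), and with the block they were called, at an adjusted p of 0.00564, as were the lineage regulators, at 0.0486, lower by the test and the mean (-0.10) with a median of 0.01. Both gave an adjusted p of 0.961 with an estimated correlation and the block. T cell identity genes were all slightly negative (12 of 12, median -0.08, adjusted p = 0.027) and myeloid and dendritic cell markers slightly positive (13 of 14, median 0.09, adjusted p = 0.00482), and with an estimated correlation both gave an adjusted p of 0.919. Both shifts lay mainly between the replicate 1 libraries, and between the replicate 2 libraries members of both lists moved both ways. In RelB-KO against WT, Lyz2 was at 5.787 against 5.205 in replicate 1 and at 4.72 against 4.727 in replicate 2. Most of the myeloid and dendritic cell markers lay under the expression minimum. Of NF-kB target genes, Ebi3 rose (0.51) and Ltb fell (-0.43) when adjusted over the list alone, at the edge of the threshold, and the set was not called (adjusted p = 0.421). Foxp3 (0.03 ± 0.12), Il2ra (0.18 ± 0.13), Ctla4 (-0.03 ± 0.13) and Il10 (-0.23 ± 0.33) did not pass. Counts of called lists ran from 1 without WT replicate 1 to 7 without WT replicate 2, and were 9 and 12 without RelB-KO replicate 1 and 2, against 3 with all libraries and 5 with the block.

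DKO cells differed from WT in few single genes. Only the targeted Relb (-3.67 ± 0.13, adjusted p = 0.000759) and Nfkb2 (-3.14 ± 0.20, adjusted p = 0.0145) were called, and 715 genes had an unadjusted p under 0.05, close to what no change would give. The replicate block brought the number of called genes to 9. Those that rose were Ikzf3, the lymphoid transcription factor Aiolos (0.71 ± 0.08), and Gsto1, a glutathione transferase (0.70 ± 0.07). Those that fell with the targeted genes were Kcnf1, a potassium channel subunit (-2.53 ± 0.25), Dscam (-1.51 ± 0.17), Syne2 (-1.25 ± 0.16), Serpina3g (-0.87 ± 0.08) and Ltb, lymphotoxin beta (-0.73 ± 0.09). The authors' adjusted p values call 135 genes, 65 higher and 70 lower. The count was 13 without WT replicate 2, and 1 without WT replicate 1 or either Nfkb2-KO library.

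Effector Treg genes were higher in DKO than in WT as a set, with 17 of 23 positive and a median of 0.34 (camera adjusted p = 0.00022, and adjusted p = 0.802 with an estimated correlation). Adjusted over the list alone 5 rose and 1 fell: Ebi3, a subunit of IL-35 (0.65), the maturation marker Klrg1 (1.07) and Prdm1, the regulator Blimp-1 (0.60), were among those that rose, and Cxcr3 fell (-0.45). Over all genes 0 passed with limma or with the block. All 24 cell cycle genes were positive (median 0.29, adjusted p = 0.000737, and adjusted p = 0.802 with an estimated correlation). Of these 0 passed over the list alone, and 10 did with the block. Cholesterol biosynthesis genes were higher (20 of 21 positive, median 0.15, adjusted p = 3.36e-06, and adjusted p = 0.624 with an estimated correlation). Oxidative phosphorylation was higher (median 0.08, adjusted p = 0.0335), T cell identity lower (-0.14, adjusted p = 0.0402) and NF-kB pathway components lower (-0.09, adjusted p = 0.000419), the last with Relb and Nfkb2 as the members that passed. With an estimated correlation the adjusted p of all 3 was 0.802. Among markers of other cell types B cell markers had a median of -0.05 (adjusted p = 0.103) and myeloid and dendritic markers 0.05 (adjusted p = 0.267). Foxp3 (-0.10 ± 0.12), Il2ra (0.49 ± 0.13, adjusted p = 0.861), Ctla4 (0.25 ± 0.13) and Il10 (0.19 ± 0.33) did not pass. With the block glycolysis (median 0.13, adjusted p = 0.015) and ribosomal proteins (0.11, adjusted p = 0.00075) were also called higher, each with an adjusted p of 0.682 with an estimated correlation. The doubt about ribosomal protein values given for Nfkb2-KO holds here too. Gapdh (-5.65) and Cycs (-2.48), genes of glycolysis and respiration with such copies, were also far lower in replicate 1. Values of the glycolysis and oxidative phosphorylation lists may therefore share the doubt in every comparison. Of 21 lists 6 were called with all libraries, 8 with the block, 3 without WT replicate 1 and 10 without DKO replicate 1.

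**Figure D4:**
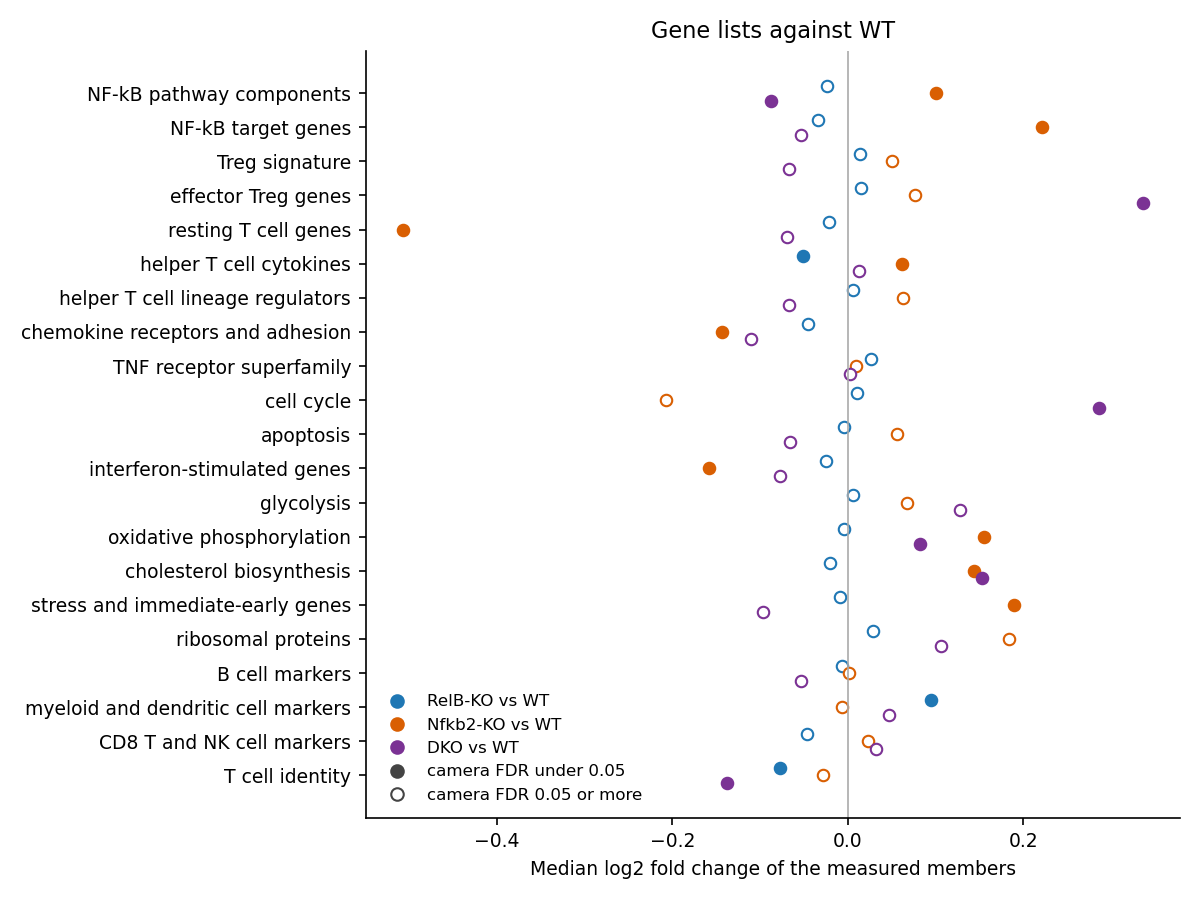
Median log2 fold change against WT (x axis) of the measured members of each of 21 gene lists, with colour for the knockout and filled points where the camera adjusted p at the preset correlation was under 0.05. Resting T cell genes stood at -0.51 in Nfkb2-KO, and effector Treg genes at 0.34 in DKO; no list passed with an estimated correlation.

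The comparison of DKO with Nfkb2-KO shows the effect of removing RelB from cells that already lack Nfkb2. Several genes that were high in Nfkb2-KO were low in DKO: Dscam differed by -3.96 ± 0.23 (adjusted p = 0.00333), Thsd7a by -3.63 ± 0.35, Aldh1a2 by -2.91 ± 0.12 (adjusted p = 0.000917), Sh3pxd2b by -2.75 ± 0.17, Hspg2 by -2.58 ± 0.20, Scin by -2.54 ± 0.24, Whrn by -2.43 ± 0.17 and Vcam1 by -2.07 ± 0.17. Myo3b (-2.65 ± 0.25) and Relb (-3.93 ± 0.13) completed the 10 named genes that were lower. The 10 named genes that were higher were Satb1 (1.66 ± 0.22), the phosphodiesterases Pde2a (1.66 ± 0.23) and Pde3b (1.18 ± 0.14), Ikzf3 (1.49 ± 0.13), Stab1, a scavenger receptor (1.48 ± 0.17), Itgb3, an integrin subunit (1.45 ± 0.16), Gbp1 (1.37 ± 0.19), Nid2, a basement membrane protein (1.15 ± 0.12), Plxnd1 (1.095 ± 0.11) and Il6ra (1.09 ± 0.11). Nid2 shares part of its locus with Rtraf.

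In total 106 genes were called between DKO and Nfkb2-KO, 17 higher and 89 lower, and 693 with the replicate block (285 higher, 408 lower). Among the genes added by the block were Gzmb (1.87 ± 0.15), Igfbp4 (1.79 ± 0.25), Adarb1 (1.35 ± 0.19) and Klrg1 (1.23 ± 0.24). Without WT or RelB-KO libraries, 1 at a time, 57 or 58 were called. The count was 14 and 23 without Nfkb2-KO replicate 1 and 2, and 12 and 8 without DKO replicate 1 and 2.

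Lists moved in DKO against Nfkb2-KO as follows. Resting T cell genes were higher (14 of 17 positive, median 0.41, adjusted p = 3.6e-05), with 2 rising over all genes and 5 over the list alone, among them Igfbp4 and Foxp1 (0.70). NF-kB target genes were lower (median -0.28, adjusted p = 0.00044), with Ltb falling over all genes (-1.21) and Bcl2a1a (-0.49) and Traf1 (-0.95) among 5 that fell over the list alone, while Ebi3 rose (0.65). NF-kB pathway components were lower (median -0.20, adjusted p = 1.9e-06), including Birc2 (-1.01) and Traf2 (-0.47). The deleted Relb (-3.93) is also a member, so part of that call follows from the deletion itself. Helper T cell cytokines fell as a set (adjusted p = 0.024), with Il21 (-0.77), Lta (-0.67), Il17a (-0.50) and Tnfsf11 (-0.40) passing over the list alone. Among the lineage regulators Il23r (-0.69) and Runx3 (-0.90) were among those that fell and Maf rose (0.82) over the list alone, and the set was not called (adjusted p = 0.303). B cell markers were lower (adjusted p = 0.00831, median 0.00), through Cd74 (-1.72), Blk (-0.27), H2-Ab1 (-0.75) and H2-Aa (-0.43). With an estimated correlation the adjusted p was 0.476 for each of the sets called in this paragraph.

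Cell cycle genes were higher in DKO than in Nfkb2-KO as a set (23 of 24 positive, median 0.42, adjusted p = 6.83e-05, and adjusted p = 0.67 with an estimated correlation). Of these 0 passed over the list alone with limma, with Mki67 at 0.92 ± 0.37, and 16 did with the block. Stress and immediate-early genes were lower (median -0.25, adjusted p = 0.0015), with Atf3 falling over the list alone (-0.84), chemokine receptors and adhesion genes higher (0.20, adjusted p = 0.0442), and interferon-stimulated genes and glycolysis higher (0.09 each, adjusted p = 0.0454 for both), with Gbp3 (0.96) and Gbp2 (1.19) rising over the list alone. With an estimated correlation the adjusted p values were 0.476, 0.476, 0.67 and 0.653. Effector Treg genes did not pass as a set (adjusted p = 0.0538), although 7 rose and Havcr2 fell (-0.71) over the list alone, with Icos (0.78) and Klrg1 among those that rose. The block added calls for the Treg signature (median -0.07, adjusted p = 0.0497), myeloid and dendritic cell markers (0.06, adjusted p = 0.0221) and oxidative phosphorylation (-0.08, adjusted p = 0.0196), each with an adjusted p of 0.677 with an estimated correlation. For most of the myeloid and dendritic cell markers the rise was larger between the replicate 1 libraries, and most lay under the expression minimum. Lyz2 in DKO against Nfkb2-KO was at 5.607 against 5.085 there and at 4.74 against 4.716 in replicate 2.

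When Nfkb2 was removed from cells that already lacked RelB, Nfkb2 was the 1 gene called between DKO and RelB-KO (-2.92 ± 0.20, adjusted p = 0.0458), with 398 at an unadjusted p under 0.05, fewer than no change would give. Podnl1 was also called with the replicate block (0.82 ± 0.09). The limma count was 0 without any 1 library other than DKO replicate 2, and 2 without that library. Effector Treg genes (20 of 23 positive, median 0.24, adjusted p = 0.000148), cell cycle genes (24 of 24, 0.28, adjusted p = 0.00026) and cholesterol biosynthesis genes (20 of 21, 0.18, adjusted p = 2.37e-07) were higher as sets. With an estimated correlation the adjusted p values were 0.675, 0.874 and 0.476, and 0 members passed over the list alone with limma. With the block 7 effector Treg genes, 8 cell cycle genes and 5 cholesterol biosynthesis genes rose over the list alone. Oxidative phosphorylation (0.09, adjusted p = 0.00628), helper T cell cytokines (0.05, adjusted p = 0.00628) and CD8 T and NK cell markers (0.03, adjusted p = 0.00534) were the other lists called, with adjusted p values of 0.874, 0.587 and 0.824 with an estimated correlation. Of 21 lists 6 were called with all libraries, 10 with the block, 12 without RelB-KO replicate 2 and 11 without DKO replicate 1.

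The knockouts of single genes differed from each other in 110 genes, 91 higher and 19 lower in Nfkb2-KO than in RelB-KO, and in 615 with the replicate block (384 higher, 231 lower). Apart from Relb, the named genes that were higher were Dscam (3.79 ± 0.23), Thsd7a (3.60 ± 0.35), Sh3pxd2b (2.93 ± 0.17), Myo3b (2.76 ± 0.25), Aldh1a2 (2.61 ± 0.12), Hspg2 (2.57 ± 0.20), Scin (2.49 ± 0.24), Whrn (2.27 ± 0.17) and Asb2 (1.93 ± 0.24). Pde2a (-1.87 ± 0.23), Gbp1 (-1.86 ± 0.19), Itgb3 (-1.34 ± 0.16), Il6ra (-1.29 ± 0.11), Stab1 (-1.12 ± 0.17), Ikzf3 (-1.12 ± 0.13), Tanc2 (-1.08 ± 0.11), Matn2 (-1.06 ± 0.12) and Nid2 (-1.02 ± 0.12) were lower, as was Nfkb2. Resting T cell genes were lower (median -0.42, adjusted p = 0.000102), and NF-kB target genes (0.21, adjusted p = 0.00173) and oxidative phosphorylation (0.17, adjusted p = 0.000326) higher, each with an adjusted p of 0.513 with an estimated correlation. Helper T cell cytokines were higher (0.17, adjusted p = 0.000139, and adjusted p = 0.436 with an estimated correlation), with 7 rising over the list alone. Cholesterol biosynthesis (0.18, adjusted p = 0.00177), NF-kB pathway components (0.13, adjusted p = 0.00315), stress and immediate-early genes (0.22, adjusted p = 0.0329) and B cell markers (0.05, adjusted p = 0.0283) were also higher, each with an adjusted p of 0.513 with an estimated correlation. The pathway components include the deleted genes, Relb (4.40) and Nfkb2 (-3.73), whose differences follow from the deletions. Interferon-stimulated genes (-0.17, adjusted p = 0.00732) and myeloid and dendritic cell markers (13 of 14 negative, -0.09, adjusted p = 0.032, and 0.0014 with the block) were lower, with adjusted p values of 0.563 and 0.697 with an estimated correlation. For most of these markers the fall was larger between the replicate 1 libraries. Lyz2 was at 5.085 against 5.787 there and at 4.716 against 4.72 in replicate 2. The block added cell cycle (-0.19, adjusted p = 0.0129) and ribosomal proteins (0.15, adjusted p = 0.000994), with adjusted p values of 0.652 and 0.557 with an estimated correlation. Ribosomal protein values are in doubt here as in the comparisons with WT. The count was 49 without either WT library, 53 and 55 without DKO replicate 1 and 2, 13 and 31 without Nfkb2-KO replicate 1 and 2, and 9 and 12 without RelB-KO replicate 1 and 2.

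The effect of deleting Nfkb2 was then set beside its effect in cells without RelB, in contrasts that share no library. The 40 genes that were higher in Nfkb2-KO than in WT had a median of 1.04 there and of 0.01 between DKO and RelB-KO, where 22 of the 40 (55%) were positive. The 6 genes that were lower, Nfkb2 left out, had medians of -1.11 and -0.18, and 4 were negative in both. In the model with the replicate block the medians were 0.57 and 0.02 for 264 genes that were higher and -0.52 and -0.11 for 137 that were lower. Of these, 153 of the 264 (57.95%) and 106 of the 137 (77.37%) had the same sign in both contrasts. Across all 13797 genes, which are not independent replicates, the fold changes of the pair of contrasts correlated at r = 0.308 (Spearman 0.384). The correlation fell to 0.070 without DKO replicate 2 and lay between 0.137 and 0.168 without WT replicate 1, Nfkb2-KO replicate 2 or either RelB-KO library. These values used the model without the block. Leaving out 1 library there puts part of the replicate difference into 1 contrast of the pair, which can itself move r.

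The same comparison for RelB used the genes called between DKO and Nfkb2-KO. Relb left out, the 88 that were lower in DKO had a median of -0.92 there and of -0.12 between RelB-KO and WT, where 78 (88.6%) were also negative. The 17 that were higher had medians of 1.095 and 0.24, and 15 (88.2%) were positive in both. In the model with the replicate block 329 of 407 genes that were lower (80.8%) and 210 of 284 that were higher (73.9%) had the same sign. Across all genes r was 0.367 (Spearman 0.234), and it was lower without any 1 library, from 0.136 without RelB-KO replicate 2 to 0.286 without Nfkb2-KO replicate 2. Here too the replicate difference enters 1 contrast of the pair when a library is left out, which can itself move r.

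**Figure D5:**
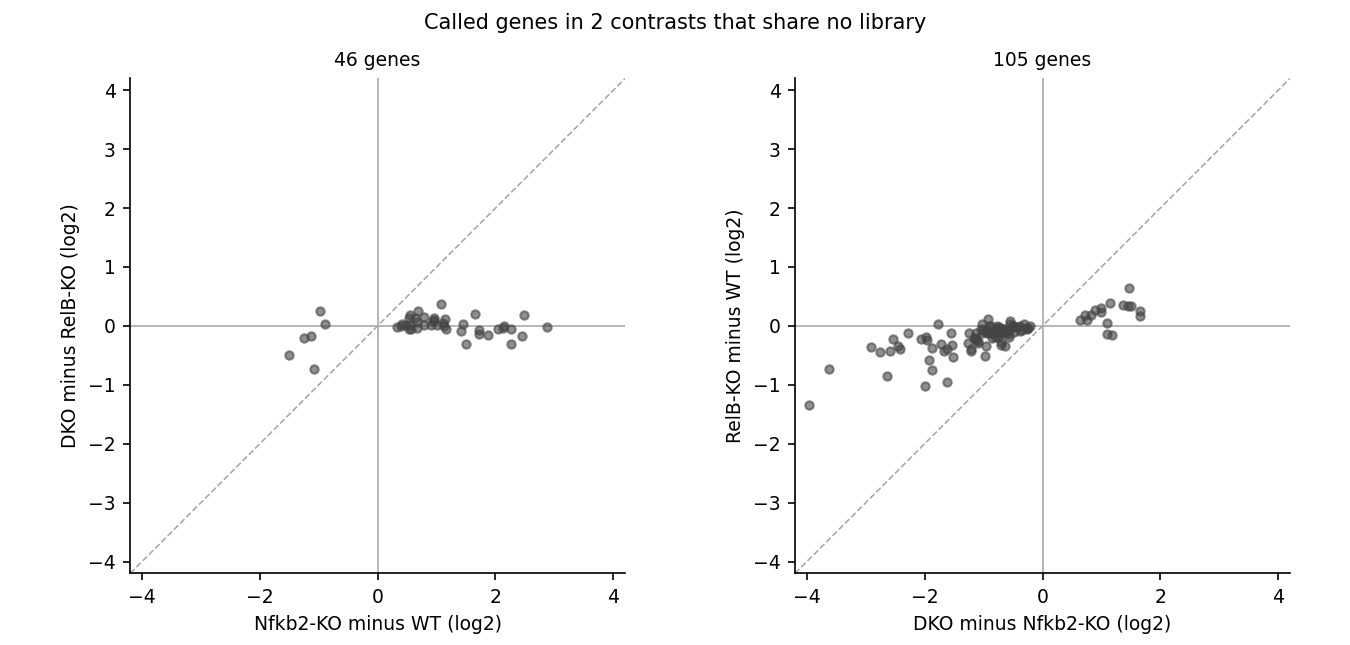
Log2 fold changes of called genes in pairs of contrasts that share no library, 1 point per gene, with the dashed line marking equal change. On the left are 46 genes called between Nfkb2-KO and WT (x axis) against DKO minus RelB-KO (y axis). Their y medians were 0.01 for genes that were higher in Nfkb2-KO and -0.18 for genes that were lower. On the right, genes called between DKO and Nfkb2-KO (x axis) mostly keep their sign between RelB-KO and WT (y axis). Their y medians were 0.24 for genes that were higher in DKO and -0.12 for genes that were lower.

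The interaction test asked, gene by gene, whether the effect of RelB loss differed with and without Nfkb2. Aldh1a2 was the 1 gene called (-2.56 ± 0.17, adjusted p = 0.0386), with 614 at an unadjusted p under 0.05, fewer than no change would give. The difference of Aldh1a2 with RelB loss was -0.35, not called, in the presence of Nfkb2 and -2.91 without Nfkb2. Aldh1a2 averaged 6.66 over all libraries, near the expression minimum of 6.23 for named genes, and was 2.26 higher in Nfkb2-KO than in WT. The shrunken scale can make a fall from the lower WT level too small. Part of this interaction may therefore come from the scale, which was not tested. With the replicate block 65 genes were called, 16 with a positive and 49 with a negative value, among them Hspg2 (-2.16 ± 0.16), Dscam (-2.63 ± 0.24), Sh3pxd2b (-2.31 ± 0.21) and Ikzf3 (1.15 ± 0.11). Without the block the count was 12 without WT replicate 2, 1 without Nfkb2-KO replicate 2 and 0 without any other library, and 3 when genes with a near-identical copy were left out.

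Few limma calls against WT were shared in the same direction. By limma RelB-KO and DKO shared Relb, Nfkb2-KO and DKO shared Nfkb2, and RelB-KO and Nfkb2-KO shared 0 genes. With the replicate block Serpina3g joined Relb and Syne2 joined Nfkb2, while 4 genes called in both Nfkb2-KO and DKO, and 1 in both RelB-KO and Nfkb2-KO, moved in opposite directions. Independent calls would share between 0.000145 and 0.108 genes on average, and simulated libraries without change shared 0 without the block and at most 2 with it. By the authors' adjusted p values RelB-KO and DKO shared 11 genes in the same direction and 0 in opposite directions, and Nfkb2-KO and DKO 26 and 20. RelB-KO and Nfkb2-KO shared 0 in the same direction, while 6 of the 13 RelB-KO calls, all lower, were called higher in Nfkb2-KO: Ltb, Ptpn5, Pkdcc, Serpina3g, Marcksl1 and Dscam. Overlaps with all libraries use the same 2 WT libraries, so part of an overlap can come from the shared controls. These were not split, as each part would hold 1 library. Leaving out WT replicate 2 leaves WT replicate 1, with its low Xist and high Y-linked transcripts, as the only WT library. Sex-linked genes can then enter each overlap, which was not tested. Without WT replicate 2 the limma overlaps in the same direction were 11 (RelB-KO and Nfkb2-KO), 12 (RelB-KO and DKO) and 12 (Nfkb2-KO and DKO), and the last was 0 without WT replicate 1 or either Nfkb2-KO library.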

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

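The tests on the sex of the animals, on markers of other cell types and on the need for RelB were chosen only after the result was seen, and the condition on marker expression was added after the marker test had been run, which turned its outcome from evidence against such cells to open. The effect of RelB loss differed with and without Nfkb2 by a test of the difference itself, which called 1 gene without the replicate block and 65 with it. Negative values mean that RelB loss lowered a gene more where Nfkb2 was absent. The interaction was -2.56 for Aldh1a2, and among the genes that passed only with the block were Dscam (-2.63), Sh3pxd2b (-2.31), Hspg2 (-2.16), Whrn (-2.04), Fsd1l (-1.80), Igsf3 (-1.49), Nek6 (-1.21), Ikzf3 (1.15) and Gzmb (1.99). Nek6 shares part of its locus with Psmb7. Among the genes just named, mean values over all libraries ran from 6.46 (Hspg2) to 12.25 (Ikzf3). For those near the expression minimum of 6.23, such as Hspg2 and Aldh1a2 (6.66), the shrunken scale may account for part of the interaction, which was not tested.

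Among gene lists the interaction was negative for NF-kB pathway components (median -0.18, adjusted p = 0.000565), NF-kB target genes (-0.25, adjusted p = 0.000565), stress and immediate-early genes (-0.19, adjusted p = 0.00105) and B cell markers (-0.0496, adjusted p = 0.0195). It was positive for resting T cell genes (0.52, adjusted p = 2e-06), cell cycle (0.40, adjusted p = 0.000368), chemokine receptors and adhesion (0.17, adjusted p = 0.00373), interferon-stimulated genes (0.093, adjusted p = 0.00664), glycolysis (0.0567, adjusted p = 0.0195) and CD8 T and NK cell markers (0.0390, adjusted p = 0.029). None of these 10 lists passed with an estimated correlation, where the adjusted p values ran from 0.572 to 0.68, or with the rotation test fry, where they ran from 0.573 to 0.755. With the replicate block camera called 11 lists. The Treg signature was added as negative (median -0.07, camera adjusted p = 0.0379, against 0.0823 without the block), with an adjusted p of 0.753 with an estimated correlation and the block.

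The 40 genes that were higher in Nfkb2-KO than in WT, which include Aldh1a2, Dscam and Vcam1, had a median near 0 (0.01) between DKO and RelB-KO. The sex-linked transcripts of WT replicate 1 are argued against as the cause of the rise, since all 40 were also higher in Nfkb2-KO than in RelB-KO, by a median of 1.08 and a ratio of 1.04 to the median against WT. With WT replicate 1 left out, 26 of the 40 were called in that contrast, and 40 with the block, in a comparison that shares the Nfkb2-KO libraries with the first. Markers of B, myeloid, CD8 T and NK cells, class II genes and Cd74 left out, had a median of -0.00392 (SD 0.126, 36 markers), but 7 of the 36 reached the expression minimum and Cd74 and H2-Ab1 rose, so such cells stay open. It also stays open that the rise in Nfkb2-KO may need RelB, since the ratio of the medians between the contrasts without shared libraries was 0.00822, a hypothesis found and tested on the same libraries and confounded with any difference between the animals.

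Against WT, leaving out WT replicate 1 gave 0 calls for Nfkb2-KO (limma, 1472 at an unadjusted p under 0.05 with all libraries) and leaving out WT replicate 2 gave 29. With the block the same omissions gave 176 and 308, against 402. Without WT replicate 1 and without the block the median standard error of the 40 genes was 0.154, against 0.119, and their median fold change 0.957, against 1.04. With 1 WT library left, a larger standard error and fewer residual degrees of freedom follow from the design. Leaving out 1 library also unbalances the replicate number, for which the model without the block has no term. Other causes were not tested.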

How the results depend on the processing

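Quantile normalization, the pseudocount, a mean un-logged value of at least 32, leaving out genes with a near-identical copy, X- and Y-linked members or Relb and Nfkb2, the authors' values and leave-one-out within the blocked model were chosen only after the result was seen. Every call of a gene in the 7 contrasts without the replicate block was also made with it. Of 62 values of named genes that were called, none reversed in any setting; 8 lost the call with no filter, 9 with a mean un-logged value of at least 32, 1 under quantile normalization, 41 of 61 with only the groups compared, and between 15 and 48 without any 1 library. Other size factors and another count-based test were named in advance but need counts, and were not run. Read depth is unknown, so what it limits could not be computed. Leaving out a library leaves a group with 1, assumed to vary like the others. Without WT replicate 2 the WT library left is replicate 1, with high Y-linked transcripts, so sex-linked genes can enter the counts against WT.

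With the replicate block the counts were 2 (RelB-KO against WT), 402 (Nfkb2-KO against WT), 9 (DKO against WT), 693 (DKO against Nfkb2-KO), 2 (DKO against RelB-KO), 615 (Nfkb2-KO against RelB-KO) and 65 (interaction), and list counts moved to 5 (RelB-KO against WT) and 10 (DKO against RelB-KO). The block removes the replicate difference from the residual spread; beyond that the cause was not tested. Overlaps in the same direction with the block were 2 (RelB-KO and DKO) and 2 (Nfkb2-KO and DKO), and by the authors' adjusted p values 11 and 26. The authors' counts were 13, 739 and 135 for RelB-KO, Nfkb2-KO and DKO against WT, and the cause was not tested. In Nfkb2-KO against WT the count was 20 with no filter, 15 at a mean of at least 32, 26 at a log2 fold change of at least 1 and 1 with only the groups compared. With only those groups it was 0 (DKO against WT; limma, 715 at an unadjusted p under 0.05 with all groups), 13 (DKO against Nfkb2-KO), 0 (DKO against RelB-KO) and 13 (Nfkb2-KO against RelB-KO), where fewer samples leave fewer degrees of freedom. At a log2 fold change of at least 1 the count was 50 in DKO against Nfkb2-KO and 57 in Nfkb2-KO against RelB-KO. Without genes that have a near-identical copy it was 160 in DKO against Nfkb2-KO and 3 for the interaction, and in DKO against RelB-KO it was 0 with no filter and 0 at a mean of at least 32; the cause was not tested. With an estimated correlation, and with fry, 0 lists passed in each of the 7 contrasts. Without X- or Y-linked members, Relb and Nfkb2 the list counts were 3, 9, 5, 11, 6, 11 and 10, in the order of contrasts above.

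Without 1 library at a time, counts ran from 1 to 12 (12 without WT replicate 2) for RelB-KO against WT, 0 (without WT replicate 1) to 29 for Nfkb2-KO, and 1 to 13 (13 without WT replicate 2) for DKO. They ran from 8 (without DKO replicate 2) to 58 in DKO against Nfkb2-KO, 0 to 2 in DKO against RelB-KO, 9 (without RelB-KO replicate 1) to 55 in Nfkb2-KO against RelB-KO and 0 to 12 for the interaction. With the block they ran, in that order, from 1 to 34, 143 to 486, 4 to 55, 135 to 804, 1 to 4, 229 to 782 and 11 to 123. List counts ran from 1 to 12, 9 to 10, 3 to 10, 9 to 14, 4 to 12, 8 to 11 and 7 to 12. Overlaps ran from 0 to 11 (RelB-KO and Nfkb2-KO), 1 to 12 (RelB-KO and DKO) and 0 to 12 (Nfkb2-KO and DKO). The correlation of the effect of Nfkb2 loss with and without RelB ran from 0.0701 to 0.312; it was 0.587 over called genes and 0.196 over these without Relb and Nfkb2. For RelB loss it ran from 0.136 to 0.286, and was 0.667 and 0.788. Leaving out 1 library without the block unbalances the replicate number in 1 contrast of each pair, which can itself move the correlation.

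All values that reversed were differences from WT that had not been called. In RelB-KO, Foxp3 ran from -0.0455 (without RelB-KO replicate 1; -0.0338 without WT replicate 1) to 0.104, Ctla4 from -0.0668 to 0.0099 (without RelB-KO replicate 2; 0.00141 without WT replicate 2) and Il10 from -0.495 to 0.0443 (without WT replicate 2). In Nfkb2-KO, quantile normalization gave 0 for Il2ra and -0.0929 for Ctla4, and Ctla4 ran from -0.0723 (without Nfkb2-KO replicate 2; -0.00883 without WT replicate 1) to 0.114. In DKO, Foxp3 ran from -0.22 to 0.0217 (without DKO replicate 2), and Il10 from -0.299 (without DKO replicate 2; -0.0796 without WT replicate 1) to 0.679. The cause was not tested.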

Other observations

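The tests on other cell types, on a swap of WT replicate 1 and on the genes lower in DKO than in Nfkb2-KO were chosen only after the result was seen, and the test on T cell identity genes took the place of the test on markers after that had been run. Replicate 1 and replicate 2 differed in every genotype. In all 4, 92 genes differed by at least 2 log2 units the same way, 27 higher in replicate 1 and 65 in replicate 2. Gapdh (-5.65), Ppia (-5.80), Rps13 (-5.29) and Rpl9 (-5.26) were far lower in replicate 1; these genes were picked after their values were seen. Of those 92, 72 could be searched for near-identical processed pseudogene copies, and 55 (76.4%) had one, against 722 of 12106 other genes (5.96%), a ratio of 12.8 (Fisher p = 1.43e-51 across genes, which are not independent).

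Reads shared with such copies and counted differently may therefore lie behind the largest differences. Copies found at these thresholds do not account for the rest: over 11226 genes without one, the lowest correlation of the replicate difference between genotypes was 0.555. Shorter or less similar copies would be missed by the search. Rps29 (-5.79), for which no copy was found, was also far lower in replicate 1. Shared reads are therefore not excluded in these genes. Cells of other types are argued against as the cause of changes this large in genes that all cells use, since 12 T cell identity genes, which such cells would dilute, had a median difference of 0.0520 (SD 0.0939), against a median size of 3.34 in the 92 genes. Markers of other cell types had a median difference of 0.0352 (SD 0.215, 41 markers), with 8 of the 41 at the expression minimum or above, so a small share of such cells is not excluded. Transcript length stays open, with a Spearman correlation of 0.171 across 12934 genes, between the bounds set for it. The design gives no biological explanation, and none within the Treg cells was tested.

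WT replicate 1 had Xist at 8.17, against 14.6 to 15.1 in the other libraries, and high Ddx3y (11.60), Eif2s3y (11.27), Kdm5d (10.88) and Uty (7.08). A swap with a knockout library is argued against, since Relb and Nfkb2 in this library lay 3.58 and 2.94 above the highest library in which each is deleted. The Y-linked values, with Ddx3y between 4.25 and 4.35 in the other libraries, argue against female animals alone behind this library. Whether males gave part or all of it stays open. Genes that escape X inactivation could not decide this, as they shifted by a median of -0.189 but moved both ways (Kdm6a -0.73, Kdm5c -0.33, Eif2s3x -0.04, Ddx3x 0.06). The labels used here give no sex for the libraries.

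A hypothesis tested here was that RelB loss shifts genes the same way whether or not Nfkb2 is present. Of the 88 genes lower in DKO than in Nfkb2-KO, 88.6% were also lower in RelB-KO than in WT, a contrast that shares no library with the first but whose libraries entered the spread of the model that called these genes, against 48.2% of all tested genes. The share was lowest without WT replicate 2, at 84.1%. Genes are not independent replicates, so these shares are descriptive. The shifts with Nfkb2 present were smaller, with a median of -0.12 against -0.92.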
